A study of Mus musculus with 20 samples.

How the data were processed

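RNA was measured in 20 libraries of motor neurons derived from mouse embryonic stem cells, 2 libraries in each of 10 groups: NIL (labelled spinal) and NIP (labelled cranial), each at 0 h and at 12 h and 36 h with and without 20 µM cyclopiazonic acid. Per the labels, total RNA was extracted with a column kit that included DNase digestion, ribosomal RNA was depleted, and libraries followed the KAPA RNA HyperPrep protocol. Depletion of ribosomal RNA keeps transcripts without a poly(A) tail and reads from introns and precursors, so counts at a gene cover more than finished mRNA. Reads at Rn45s, the ribosomal precursor gene, may come from the precursor or from ribosomal RNA that the depletion left, and the counts cannot separate these. The labels state the later times as 12 h and 36 h in the sample titles and the extraction text, and as 6 h and 12 h in the treatment text and the series design; the titles set the groups.

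The deposited files hold read counts per gene, whole numbers for 24421 gene symbols and 5 summary lines for reads not assigned to a gene. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.3.2, HTSeq 0.6.1p1 and Picard, and the GRCm38 (mm10) build. The notes used here give neither the strand setting nor the annotation release, and counts by symbol cannot separate overlapping genes if strands were pooled. HTSeq leaves out reads that map to more than 1 place, which were 18.2% to 52.6% of reads across the libraries, so genes with close paralogs can be undercounted. Reads outside genes were 7.77% to 18.7% and ambiguous reads 0.156% to 0.458%. The count files list no genes of the mitochondrial genome.

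Gene reads ranged from 7996454 to 30321152 with a median of 19.8 M, and 15642 to 17296 genes had a count. Counts of the replicates of a group differed by more than sampling noise in every group (chi-square per degree of freedom 31.9 to 336), so no library was a copy of another in its group. The first principal components of log2 CPM held 51.0%, 16.7% and 10.1% of the variance.

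Genes were filtered with edgeR's filterByExpr by group, which kept 14792 genes, and libraries were scaled with TMM factors. A single edgeR quasi-likelihood model with robust estimates, a mean per group and 10 residual degrees of freedom gave 15 comparisons, and p-values were adjusted by the method of Benjamini and Hochberg within each comparison with a threshold of 0.05. CPM values use the scaled library sizes. The biological coefficient of variation was 27.5%. A fold against a group at 0 counts was taken against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact 95% counting interval.

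The replicate number comes from the titles. It was not part of the model fixed before the data were examined, and a fit with it as a block was fixed beforehand as an alternative. The deviations of replicate 1 from replicate 2 correlated across genes in each of 45 pairs of groups (r from 0.24 to 0.76, median 0.47; 0.57 within a line and 0.42 between lines), so the numbers pair libraries across groups. With the block the coefficient of variation was 15.7% and residual degrees of freedom 9, and values "with the block" stand beside each result whose call or count they changed.

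Before the data were examined, 33 lists of genes were fixed from textbook knowledge: ER stress and related pathways, neuronal functions, and markers of other cell types that such cultures could hold. Each list of at least 5 tested genes was compared with the other genes by camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Counts "over the list alone" adjust p-values within the list. The "spread" of a median over genes is its standard deviation when the genes are resampled. Genes of a list are not independent, and this spread leaves out variation between libraries, so it is likely too small. The estimated correlation comes from the fit without the block unless the block is named with it. The residuals of that fit hold the differences between replicate sets, which genes of a list can share. The estimate, and the adjusted p that uses it, can therefore be too high. With it 5 and 5 lists passed in NIL after 12 h and 36 h of CPA, and 6 and 5 in NIP. For the change of response with time in NIP 2 passed, and 0 in each other comparison. Genes named in the text follow a rule also fixed before the data were examined: the 6 largest rises and the 6 largest falls among genes that passed with at least 5 CPM in the higher group and no overlap between the groups, up to 4 members of each list with the smallest p, and 14 genes of motor neuron type and ER stress. The text names a part of them. Arid5a, Fgf15, Nrn1 and Thbs1 are also named in comparisons where the rule did not pick them, after their values were seen.

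Alternatives fixed before the data were examined were DESeq2's Wald test, DESeq2 size factors in edgeR, no low count filter, a filter of at least 1 CPM in 4 libraries, removal of the 20 most abundant genes, the 10 libraries of 1 line alone, the replicate block, and leaving out each library of a comparison in turn; the fit then assumes that the remaining library of a group varies like the others. Without a block, a group left with 1 library also sets 1 replicate set against both, so differences between sets enter the comparison. Fits without both libraries with over 30% of gene reads on Rn45s were added after seeing the data. Genes were placed with GENCODE M21 (GRCm38).

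The tests were tried on simulated data with 50 genes at each of 4 fold sizes and replicate sets that differed by each gene's set effect in the block fit. That effect was the same in every group and the dispersions came from the block fit, so the block's assumptions held by construction. These libraries need not meet them, so the block's recovery and false calls may not carry over. At 1.5-, 2-, 4- and 8-fold the fit without a block recovered 1, 9, 40 and 45 of 50 genes, with 0 of the unchanged genes called, and the block 2, 32, 47 and 48, with 9 unchanged genes called. For a difference in response between lines the fit without a block recovered 0, 0, 28 and 34, and the block 0, 8, 42 and 45, with 7 unchanged genes called. The fit without a block thus missed most differences of 2-fold or less, where with replicate sets alike it recovered 31 of 50 CPA changes of 2-fold. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15. The treatment text's 6 h time has no library here, and no reads, protein or imaging data were analysed here.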

Results

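The libraries came from motor neurons made from mouse embryonic stem cells, in a series whose title places the cells in a model of amyotrophic lateral sclerosis. The labels give a pair of cell types: NIL, a spinal type, and NIP, a cranial type. In this field NIL stands for the transcription factors Neurog2, Isl1 and Lhx3 expressed together, and NIP for Neurog2, Isl1 and Phox2a. Cultures at day 2 received 20 µM cyclopiazonic acid (CPA), which blocks the SERCA pumps that fill the endoplasmic reticulum (ER) with calcium and so causes ER stress. Total RNA was collected at 0 h, and at 12 h and 36 h with and without CPA, with 2 libraries in each of 10 groups. The sample titles and the extraction text give 12 h and 36 h, while the treatment text and the design of the series give 6 h and 12 h as the later times. The titles were followed here. The question named for the series is how both types respond to protein misfolding stress.

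Gene reads per library ran from 7996454 to 30321152, with a lower median in replicate set 2 (13.2 M) than in set 1 (22.6 M). Rn45s, the precursor of ribosomal RNA, held 5.18% to 38.6% of gene reads, and a pair of libraries stood apart: untreated NIP 36 h replicate 1 at 38.6% and CPA-treated NIL 36 h replicate 2 at 38.3%, against a median of 11.6%. The replicate sets differed in cell type markers across both lines. With the replicate number as a block, 14 of 16 pluripotent stem cell genes were higher in set 2 (median log2 difference 2.93), as were 24 of 24 proliferation genes (1.41), 10 of 15 endoderm and endothelium genes (1.38) and 29 of 30 ribosomal protein genes (0.43), while 20 of 25 neuronal cytoskeleton genes were lower (-0.42). Pou5f1, a pluripotency factor, differed by 3.84, Col4a1, a basement membrane collagen, by 2.17 and Mki67, a proliferation marker, by 1.59. Replicate profiles correlated at 0.956 to 0.985 across genes (log2 CPM). The labels do not say whether replicates came from separate cultures. The marker differences above, taken over both lines, argue against a purely technical spread between the sets. P-values measure only the spread between these samples, and how many separate cultures they came from is not known. Each test below compares groups of 2 libraries, and ± after a log2 change is its standard error.

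**Figure D1:**
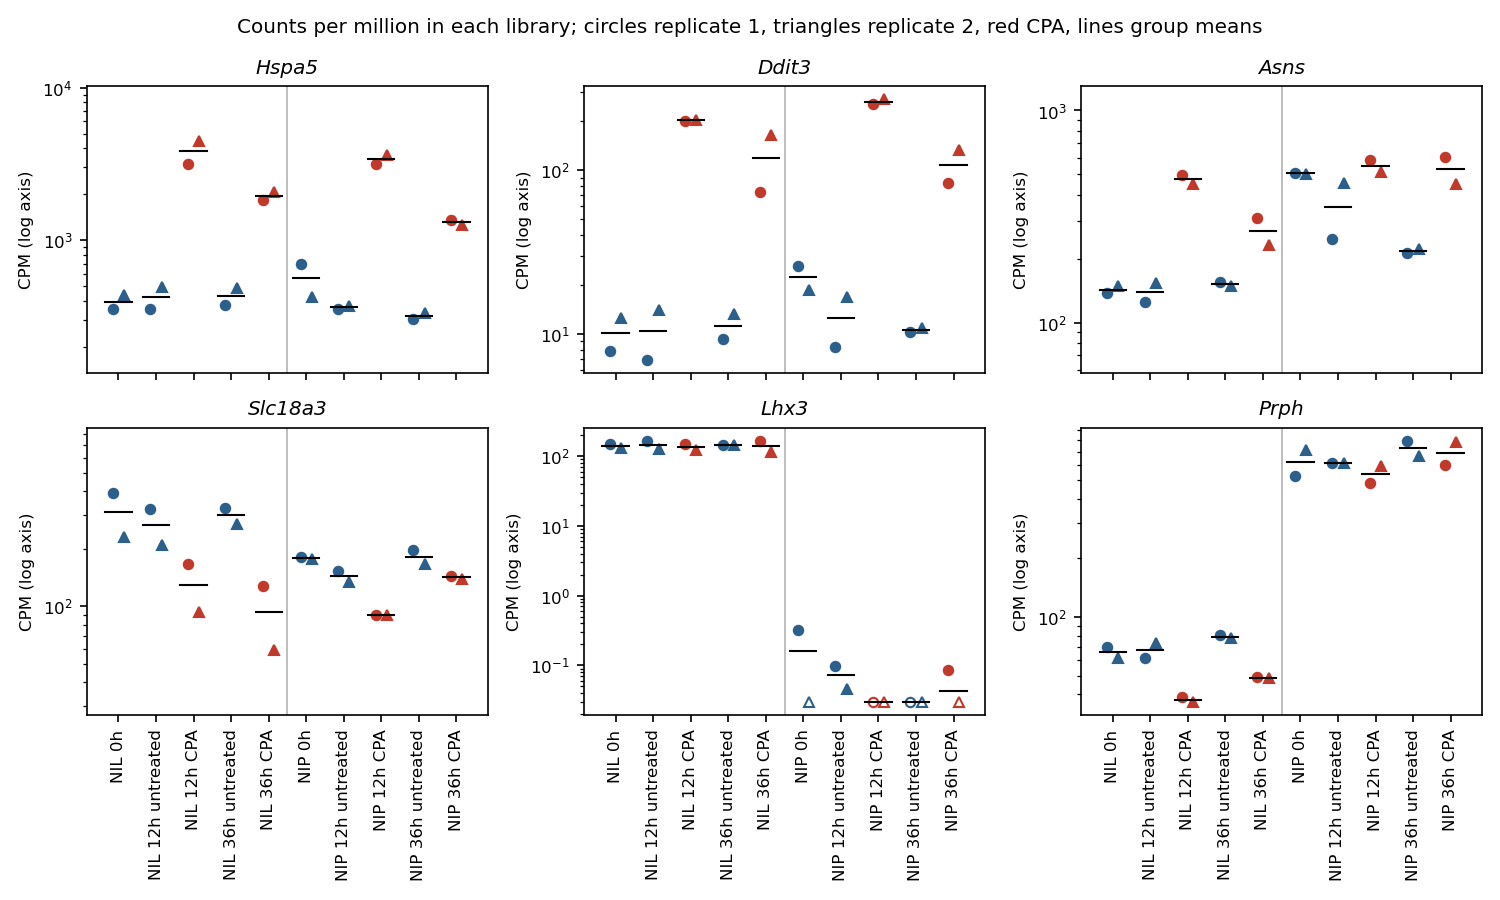
CPM (read counts scaled to library size, log axis) of 6 genes in each of the 20 libraries, by group; circles are replicate 1, triangles replicate 2, red symbols CPA, black lines the group means, and open symbols at the foot of the axis libraries with 0 counts. Hspa5 averaged 3825 CPM in NIL after 12 h of CPA against 422 CPM in the untreated cultures, and Lhx3 stayed below 1 CPM in NIP libraries.

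Untreated NIL and NIP cultures differed in transcription factors that set motor neuron type. At 0 h Lhx3, which specifies spinal motor neurons, was lower in NIP by a log2 change of -9.42 ± 0.53 (140.8 ± 14.0 CPM in NIL, mean ± SD, n = 2; adjusted p = 2e-06), and Mnx1, another spinal motor neuron factor, by -8.11 ± 0.42 (adjusted p = 2.79e-07). Isl2 (-4.85 ± 0.39) and Lhx4 (-3.64 ± 0.50) were lower as well. Phox2a, a homeobox gene of cranial motor neurons and part of the NIP factor set, was higher in NIP by 8.25 ± 1.19 (adjusted p = 0.000444), with Tlx2 (7.82 ± 0.94), a homeobox gene of autonomic neurons, and Rgs4 (5.74 ± 0.59), a regulator of G protein signalling. Lhx3 lies on chromosome 2 at 26200212 to 26208289 (minus strand, GRCm38). Counts per gene cannot separate reads of an inserted Lhx3, Phox2a, Isl1 or Neurog2 sequence from those of the cell's own copy. Isl1, present in both factor sets, had a log2 difference of -0.48 ± 0.35 (adjusted p = 0.443; 0.0488 with the replicate block).

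The spinal list held 4 of 11 measured members lower and 3 higher in NIP at 0 h (4 and 4 adjusted over the list alone, 5 and 4 with the block). Its camera adjusted p was 1.12e-07, and adjusted p = 0.107 with an estimated correlation. Of 9 cranial genes 4 were higher and 1, Gata3 (-3.90 ± 0.53), lower (5 and 2 adjusted over the list alone, 4 and 2 with the block). The cranial list had a camera adjusted p of 0.0397, and adjusted p = 0.604 with an estimated correlation, and 0.0625 with the block. Genes of the shared motor neuron list went both ways, 5 of 16 lower, such as the transcription factor Ebf2 (-2.57 ± 0.40) and the axon guidance ligand Slit2 (-2.65 ± 0.55), and 1 higher (5 and 3 over the list alone, 8 and 2 with the block, camera adjusted p = 0.221, 0.0341 with the block, adjusted p = 0.747 with an estimated correlation). The higher gene, Prph, encodes the intermediate filament peripherin (3.23 ± 0.21; adjusted p = 1.7e-06). Of 24 synaptic genes 6 were higher, Syn2 (1.84 ± 0.31) and Vamp1 (2.32 ± 0.38) among them (6 over the list alone; 10 higher and 1 lower with the block). Synaptic genes had a camera adjusted p of 0.0143, and adjusted p = 0.747 with an estimated correlation. Among ion channels, Kcnq3, a subunit of M-type potassium channels, was higher (4.83 ± 0.33), as was the calcium channel subunit Cacna2d1 (2.00 ± 0.28), and the T-type calcium channel gene Cacna1g lower (-5.62 ± 0.45).

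Genes for amino acid synthesis, transport and tRNA charging were higher in untreated NIP at 0 h, 24 of 30 (27 adjusted over the list alone, 25 with the block, median log2 difference 1.33). The amino acid list had a camera adjusted p of 2.26e-18, and adjusted p = 0.18 with an estimated correlation. They included Psat1 in serine synthesis (2.85 ± 0.41), the amino acid transporter Slc7a5 (2.60 ± 0.32) and asparagine synthetase Asns (1.82 ± 0.26), and Xbp1, a transcription factor of the unfolded protein response (UPR), was also higher (1.52 ± 0.21). Of 22 cholesterol synthesis genes 8 were higher, such as Tm7sf2 (1.53 ± 0.20) and Mvd (1.43 ± 0.29) (11 over the list alone, 18 with the block, median 0.84). Cholesterol genes had a camera adjusted p of 2.28e-06, and adjusted p = 0.702 with an estimated correlation. Markers of other cells were lower in NIP, 6 of 12 mesenchyme genes (8 over the list alone, 9 with the block, median -2.38, camera adjusted p = 8.78e-05, and adjusted p = 0.18 with an estimated correlation). Among them were the collagen Col1a1 (-3.59 ± 0.87) and Postn (2 counts in NIP; ratio of NIL to NIP 30.8, exact 95% interval 8.27 to 258). Medians were also negative for 24 proliferation genes (-1.79; 2 lower, 2 over the list alone, 23 with the block, camera adjusted p = 3.3e-05, and adjusted p = 0.746 with an estimated correlation). They were also negative for 16 pluripotent stem cell genes (-2.76; 0 lower, 9 with the block, camera adjusted p = 0.0468, and adjusted p = 0.747 with an estimated correlation) and 15 endoderm and endothelium genes (-1.40; 0 lower, 5 with the block, camera adjusted p = 0.0397, and adjusted p = 0.746 with an estimated correlation). The widest differences outside the lists were at Avpr1a, a vasopressin receptor (1 count in NIL; ratio 795, exact 95% interval 142 to 31400), and Adtrp (0 counts in NIP; at least 69.2-fold lower there against a floor of 3 counts over the group).

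In all, 1844 of 14792 genes differed at 0 h (1162 higher in NIP, 682 lower), and 3896 with the block (2109 and 1787). The count was 963 without NIL 0 h replicate 1, 945 without NIP 0 h replicate 1 and 1147 without NIP 0 h replicate 2. Of the 26 genes named above that passed, 23 passed with any of the 4 libraries left out. Slit2 had an adjusted p of up to 0.0684 and Mvd of up to 0.0581 (both highest without NIP 0 h replicate 2), and Col1a1 reached 0.151 without NIP 0 h replicate 1.

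Differences between the lines in motor neuron type genes were also present at the later untreated times, while that of amino acid genes was not at 36 h. Lhx3 was lower in NIP by -10.78 ± 0.56 at 12 h and at least 1440-fold lower at 36 h (0 counts in NIP), and Mnx1 by -8.82 ± 0.43 and -7.40 ± 0.42. Phox2a was higher by 7.77 ± 1.19 and 7.10 ± 1.13, Prph by 3.19 ± 0.21 and 3.20 ± 0.21 and Kcnq3 by 4.58 ± 0.32 at 36 h. At 12 h Kcnq3 was at 56.08 ± 12.2 CPM in NIP and 2.292 ± 0.121 CPM in NIL (adjusted p = 2.51e-06). At 12 h Otx2, a forebrain and midbrain homeobox gene, was at least 137-fold lower in NIP and Mcoln3, a lysosomal channel gene, at least 64.9-fold higher (0 counts in NIP and NIL respectively). At 36 h the hindbrain and cervical gene Hoxb4 (2.61 ± 0.31), the plasma membrane calcium pump Atp2b4 (3.60 ± 0.28) and Syn2 (2.21 ± 0.31) were higher in NIP. The amino acid list had 13 of 30 members higher at 12 h (17 over the list alone and with the block, median 0.84, camera adjusted p = 3.66e-07, and adjusted p = 0.556 with an estimated correlation). Slc7a5 was among them (1.95 ± 0.32). At 36 h the list had 0 (0 over the list alone, 1 higher and 2 lower with the block, median 0.12, camera adjusted p = 0.749). Cholesterol genes were higher at 12 h, 8 of 22 (16 over the list alone, 21 with the block, median 1.04). The cholesterol list had a camera adjusted p of 3.25e-08, and adjusted p = 0.555 with an estimated correlation.

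At 36 h the spinal list again had 4 members lower and 3 higher in NIP (4 and 3 over the list alone, camera adjusted p = 0.000173 toward lower, mean -1.27 and median 0.35 on opposite sides of 0, median 0.09 without both high-Rn45s libraries; adjusted p = 0.206 with an estimated correlation). Ion channel genes were 7 higher and 2 lower of 26 (10 and 3 over the list alone, 11 and 4 with the block, camera adjusted p = 0.017, and adjusted p = 0.883 with an estimated correlation). Of 24 synaptic genes 4 were higher (5 over the list alone, 11 with the block, camera adjusted p = 0.00363, and adjusted p = 0.971 with an estimated correlation). Proliferation genes had medians of -2.05 at 12 h (3 of 24 lower, 7 over the list alone, 24 with the block, camera adjusted p = 1.36e-06, and adjusted p = 0.854 with an estimated correlation) and -2.39 at 36 h (3, 24 and 24, camera adjusted p = 2.06e-07, and adjusted p = 0.787 with an estimated correlation). Endoderm and endothelium medians were -2.04 and -2.49 (0 of 15 lower at either time, also over the list alone; 11 and 12 with the block, camera adjusted p = 0.00294 and 0.000622, adjusted p = 0.817 and 0.787 with an estimated correlation). The 12 h comparison had 1769 genes (1136 higher, 633 lower; 4133 with the block, 2138 and 1995) and the 36 h comparison 1709 (1035 and 674; 4256 with the block, 2084 and 2172). The 12 h count was 1051 and 1131 without NIL replicates 1 and 2 and 955 and 931 without NIP replicates 1 and 2. The 36 h count was 1040, 894, 850 and 823 in the same order, and 840 without both high-Rn45s libraries. The 8 genes named at each time passed with any of the 4 libraries left out.

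CPA for 12 h in NIL cultures raised ER chaperones. Counts of a library cannot assign this or later changes to neurons or to the other cells whose markers are given above. Hspa5, encoding the ER chaperone BiP (chromosome 2, 34771970 to 34777547, plus strand), went from 422 ± 101 to 3825 ± 929 CPM (mean ± SD, n = 2), a log2 change of 3.18 ± 0.29 (adjusted p = 0.000111), with the co-chaperone Sdf2l1 (3.95 ± 0.34). The ER chaperone gene Hyou1 went from 167.5 ± 22.1 to 1343 ± 227 CPM (adjusted p = 0.000111). In the list of ER chaperones and folding enzymes 17 of 29 genes rose and 0 fell (24 adjusted over the list alone, 25 with the block, median 1.43). The chaperone list had a camera adjusted p of 7.84e-73, and adjusted p = 0.000353 with an estimated correlation. ER-associated degradation genes rose in 9 of 22 cases (11 over the list alone, 10 with the block, median 0.45, camera adjusted p = 5.49e-22, and 0.000353 with an estimated correlation). Herpud1 (3.50 ± 0.31) and Sel1l (172 ± 20.9 to 847.9 ± 157 CPM; adjusted p = 0.000111), parts of the complex that sends misfolded proteins out of the ER, were among them. ER protein entry and glycosylation genes rose in 4 of 25, such as the signal peptidase subunit Spcs2 (0.96 ± 0.19) and the glycosylation subunit Rpn1 (1.20 ± 0.24) (16 over the list alone, 13 with the block, median 0.68). Entry and glycosylation genes had a camera adjusted p of 5.14e-15, and adjusted p = 0.0544 with an estimated correlation.

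The transcription factors of the UPR rose in 4 of 12 list members (5 over the list alone and with the block, camera adjusted p = 1.29e-13, and 0.00322 with an estimated correlation): Ddit3, the stress factor CHOP, from 10.4 ± 4.98 to 200.9 ± 0.871 CPM (4.31 ± 0.49; adjusted p = 0.000554), Atf4 (2.40 ± 0.30), Atf6 (1.66 ± 0.17) and Xbp1 (1.42 ± 0.21). Of 19 targets of ATF4 and CHOP 12 rose (14 over the list alone and with the block, median 2.26, camera adjusted p = 6.16e-32, and 0.0014 with an estimated correlation). These included Atf3 (3.13 ± 0.36), the eIF2α phosphatase subunit Ppp1r15a (2.82 ± 0.33), the pseudokinase Trib3 (5.14 ± 0.81; chromosome 2, 152337422 to 152344032, minus strand) and the glutathione-degrading enzyme Chac1 (5.24 ± 0.87). Amino acid genes rose in 25 of 30 cases (30 over the list alone, 29 with the block, median 1.66, camera adjusted p = 1.12e-77, and 0.0014 with an estimated correlation). Among these were the glycine transporter Slc6a9 (4.84 ± 0.51), Slc7a5 (2.87 ± 0.33), Asns (1.77 ± 0.26) and the cystine transporter Slc7a11 (5.86 ± 1.32). Atp2a2, which encodes the SERCA pump that CPA blocks, rose by 1.45 ± 0.26 (adjusted p = 0.0092), the sodium-calcium exchanger Slc8a2 fell by 0.92 ± 0.18 on the log2 scale, and Hrk, a pro-apoptotic BH3-only gene, rose by 1.32 ± 0.27. Large rises elsewhere were at Cyb5r2 (0 counts in the untreated group; at least 73.7-fold higher), Trim66 (7.56 ± 0.93), Derl3 of the degradation machinery (7.54 ± 1.24) and Cacng3, an AMPA receptor auxiliary subunit (5.57 ± 0.70).

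Neuronal genes fell in smaller numbers. Of 16 shared motor neuron genes 2 fell, Ache, acetylcholinesterase (-1.42 ± 0.28), and Prph (-0.83 ± 0.20) (5 over the list alone, 7 with the block, median -0.51). The motor neuron list had a camera adjusted p of 0.000227, and adjusted p = 0.4 with an estimated correlation. Of 25 cytoskeleton genes 2 fell, the tubulins Tubb2b (-1.54 ± 0.28) and Tuba1a (-1.20 ± 0.26), each with close paralogs in sequence (5 over the list alone, 8 with the block, median -0.47). The cytoskeleton list had a camera adjusted p of 5.23e-07, and adjusted p = 0.489 with an estimated correlation. Nuclear-encoded respiratory chain genes fell in 2 of 28 (10 over the list alone, 7 with the block, median -0.44). Respiratory chain genes had a camera adjusted p of 2.03e-09, and adjusted p = 0.319 with an estimated correlation. Other falls were at Fabp7, a fatty acid binding protein of neural progenitors (-2.64 ± 0.45), Fxyd7, a regulator of the sodium pump (-2.22 ± 0.33), and the phosphodiesterase Pde2a (-2.04 ± 0.31).

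Altogether 327 genes changed in NIL at 12 h, 230 up and 97 down. Each went the same way in both replicate sets, which the test that picked them favours, so this is not separate replication. The count was 1174 with the block (616 up, 558 down), 703 by DESeq2, 124 with NIL libraries alone in the fit, and 117, 122, 128 and 115 without untreated replicates 1 and 2 and CPA replicates 1 and 2. Of the 35 genes named in the text that passed, 20 passed without untreated replicate 1, 26 without untreated replicate 2, 26 without CPA replicate 1 and 24 without CPA replicate 2. Those that missed at least once, with the highest adjusted p, were Trib3 (0.0675), Chac1 (0.0844), Spcs2 (0.143), Cyb5r2 (0.0774), Derl3 (0.0845) and Hspa9 (0.0681) without untreated replicate 1. Slc7a11 (0.207), Atp2a2 (0.114) and Hrk (0.179) missed without untreated replicate 2 and Pde2a (0.0516) without CPA replicate 1. Without CPA replicate 2 the highest values were at Rpn1 (0.182), Fabp7 (0.114), Ache (0.137), Prph (0.306), Tubb2b (0.175), Tuba1a (0.331) and Slc8a2 (0.138). With NIL libraries alone Spcs2 (adjusted p = 0.0512), Rpn1 (0.165), Slc7a11 (0.0634), Fabp7 (0.0706), Prph (0.0816), Tubb2b (0.15), Tuba1a (0.23) and Slc8a2 (0.0833) missed. Without the low count filter Slc7a11 (adjusted p = 0.0951), Prph (0.105) and Tuba1a (0.0648) missed, as did Prph without the 20 most abundant genes (0.0612).

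After 36 h of CPA in NIL cultures, ER stress genes were still above the time-matched untreated cultures. Hspa5 was at 1955 ± 158 CPM against 430.2 ± 80.1 CPM (log2 change 2.18 ± 0.28; adjusted p = 0.00918), Sdf2l1 rose by 2.55 ± 0.32, Herpud1 by 2.35 ± 0.30, Ddit3 by 3.41 ± 0.47, Atf4 by 1.92 ± 0.29 and Xbp1 by 1.08 ± 0.21. ER chaperones rose in 13 of 29 (21 adjusted over the list alone, 22 with the block, median 1.16, camera adjusted p = 5.45e-35, and 0.0138 with an estimated correlation). Degradation genes rose in 2 of 22 (8 over the list alone, 8 with the block, camera adjusted p = 3.53e-06, and 0.0303 with an estimated correlation). UPR factors rose in 4 of 12 (4 over the list alone, 5 up and 1 down with the block, camera adjusted p = 3.75e-07, and 0.0303 with an estimated correlation). ER protein entry genes passed in 0 of 25 (15 over the list alone, 15 with the block, median 0.68). The entry list had a camera adjusted p of 5.67e-11, and adjusted p = 0.123 with an estimated correlation. ATF4 and CHOP targets rose in 6 of 19 (11 over the list alone, 15 with the block, median 1.74, camera adjusted p = 9.29e-18, and 0.0274 with an estimated correlation). Risers included Trib3 (5.20 ± 0.81), the transcription factor Atf5 (3.12 ± 0.41) and Nupr1 (1 count in the untreated group; ratio 755, exact 95% interval 135 to 29900). Amino acid genes rose in 10 of 30 (28 over the list alone, 27 with the block, median 0.91, camera adjusted p = 6.35e-32, and 0.0303 with an estimated correlation). Among them were Slc6a9 (3.06 ± 0.47) and Slc7a5 (1.93 ± 0.31). Trim66 (5.72 ± 0.87) and Fam129a, a stress-induced gene (5.30 ± 0.98), had large rises.

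Neuronal lists were lower at 36 h in NIL. Of 16 shared motor neuron genes 3 fell: Slc18a3, the vesicular acetylcholine transporter (-1.68 ± 0.36), Ret, a receptor for GDNF family ligands (-1.36 ± 0.29), and Ache (-1.27 ± 0.28), each at an adjusted p of 0.0496 (8 over the list alone, 12 with the block, median -1.09). Shared motor neuron genes had a camera adjusted p of 2.48e-09, and adjusted p = 0.123 with an estimated correlation. Of 24 synaptic genes Syn1, a synaptic vesicle phosphoprotein, fell (-1.12 ± 0.18) (1 gene; 14 over the list alone, 18 with the block, median -0.76). The synaptic list had a camera adjusted p of 1.19e-11, and adjusted p = 0.289 with an estimated correlation. No cytoskeleton gene passed by edgeR without the block (0 of 25; 10 over the list alone, 21 with the block, median -0.86). Cytoskeleton genes had a camera adjusted p of 1.44e-12, and adjusted p = 0.299 with an estimated correlation. The neurofilament gene Nefm had -1.60 ± 0.45 (adjusted p = 0.106; 0.000149 with the block) and Mapt, encoding tau, -1.16 ± 0.28 (0.0727; 0.00293 with the block). Ion channel genes passed in 0 of 26 (4 over the list alone, 11 with the block, median -0.69, camera adjusted p = 4.12e-07, and adjusted p = 0.188 with an estimated correlation). Without both high-Rn45s libraries 0 genes of these 4 lists passed by edgeR. With the block as well, 6 motor neuron, 3 synaptic, 2 cytoskeleton and 0 ion channel genes fell, and the medians without the block were -0.69, -0.35, -0.44 and -0.44. Lhx3 (-0.03 ± 0.32; adjusted p = 0.963) and Mnx1 (-0.20 ± 0.27; adjusted p = 0.711) did not pass.

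Markers of other cells had positive medians in the same comparison: 0.42 for 24 proliferation genes, 0.63 for 16 pluripotent stem cell genes, 0.88 for 12 mesenchyme genes (mean 0.24) and 0.81 for 15 endoderm and endothelium genes. None of these genes rose by edgeR without the block, also over the list alone, where 1 mesenchyme gene was lower (camera adjusted p = 0.0889, 0.232, 0.437 and 0.0746). With the block 3, 1, 2 and 2 rose and 1 mesenchyme gene fell (camera adjusted p = 0.000212, 0.00553, 0.206 and 0.00506). The 3 calls gained in this way were lost with an estimated correlation and the block (adjusted p = 0.473, 0.426 and 0.477 for proliferation, pluripotent and endoderm genes). Without both high-Rn45s libraries the medians were 0.05, -1.42, 0.16 and 0.43, where a CPA library of set 1 faces untreated libraries of both sets. In all 145 genes changed, 66 up and 79 down. Each went the same way in both replicate sets, which the test that picked them favours. The count was 2697 with the block (1073 up, 1624 down), 700.0 by DESeq2, 4 with NIL libraries alone in the fit, 83 without the low count filter, and 84 (51 up, 33 down) without the 20 most abundant genes, a setting that moved the balance of directions, as did DESeq2 size factors in edgeR (55 up, 49 down). It was 0 without untreated replicate 1, 0 without untreated replicate 2, 514 without CPA replicate 1 and 8 without CPA replicate 2, the high-Rn45s library, and 0 without both high-Rn45s libraries (404 with the block, 264 up and 140 down). Of the 17 genes named that passed, 0 passed without untreated replicate 1 (lowest adjusted p = 0.16) or replicate 2 (0.0521), 16 without CPA replicate 1 and 4 without CPA replicate 2. Slc18a3, Ret and Ache also missed with DESeq2 size factors (adjusted p = 0.0521, 0.0521 and 0.0544), a stricter filter (0.0552, 0.0552 and 0.051) and without the 20 most abundant genes (0.0563, 0.058 and 0.0583). Without the low count filter Slc18a3, Ret, Nupr1 and Fam129a missed (adjusted p = 0.0591, 0.0591, 0.087 and 0.0677).

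In NIP cultures 12 h of CPA raised the same functional groups. Hspa5 went from 362.1 ± 9.80 to 3387 ± 315 CPM (log2 change 3.23 ± 0.29; adjusted p = 9.6e-05), Sdf2l1 rose by 4.21 ± 0.34, Herpud1 by 3.31 ± 0.31, Sel1l by 2.26 ± 0.19 and the signal peptidase gene Spcs2 by 1.13 ± 0.19. ER chaperones rose in 21 of 29 (25 adjusted over the list alone, 26 with the block, median 1.39, camera adjusted p = 1.62e-56, and 0.00105 with an estimated correlation). Degradation genes rose in 10 of 22 (12 over the list alone and with the block, median 0.71, camera adjusted p = 1.4e-19, and 0.000832 with an estimated correlation). ER protein entry genes rose in 7 of 25 (16 over the list alone, 17 with the block, median 0.70, camera adjusted p = 2.52e-13, and adjusted p = 0.0685 with an estimated correlation). UPR factors rose in 4 of 12 (7 over the list alone, 8 with the block, camera adjusted p = 3.73e-09, and 0.0157 with an estimated correlation). Ddit3 (4.39 ± 0.48) and Atf4 (1.77 ± 0.29) were among them. Xbp1 had 0.67 ± 0.21 (adjusted p = 0.0929; 0.0038 with the block). ATF4 and CHOP targets rose in 10 of 19 (17 over the list alone, 16 with the block, median 1.78, camera adjusted p = 1.63e-25, and 0.00251 with an estimated correlation). They included Atf3 (4.11 ± 0.37) and Ppp1r15a (3.70 ± 0.34). Amino acid genes rose in 16 of 30 (25 over the list alone, 23 with the block, median 1.20, camera adjusted p = 2.4e-29, and 0.0189 with an estimated correlation). Examples were Slc6a9 (3.37 ± 0.46), the serine synthesis enzyme Psph (2.14 ± 0.33) and Slc7a11 (5.52 ± 1.18; chromosome 3, 49892526 to 50443614, minus strand).

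The axon injury list moved in NIP at 12 h with 5 of 19 members up and 1 down (5 and 1 over the list alone, 6 and 1 with the block, median 0.26). The axon injury list had a camera adjusted p of 0.00162, and adjusted p = 0.0189 with an estimated correlation. The members that rose included Atf3, the growth arrest gene Gadd45a (2.49 ± 0.24; adjusted p = 0.000125), Sprr1a (4.49 ± 0.81) and Hrk (1.02 ± 0.27), and the neuropeptide gene Adcyap1 fell (-1.55 ± 0.29). Of 11 spinal genes 2 fell, Hoxb4 (-1.45 ± 0.30) and Lhx4 (-2.01 ± 0.52) (2 over the list alone, 5 with the block). Spinal genes had a camera adjusted p of 0.00058, and adjusted p = 0.112 with an estimated correlation. Of 25 cytoskeleton genes 2 fell, Tubb2b among them (-1.45 ± 0.28) (2 over the list alone, 5 with the block, median -0.46). For cytoskeleton genes camera gave adjusted p = 0.00058, and adjusted p = 0.63 with an estimated correlation. Atp2a2 rose by 1.11 ± 0.26 and Slc8a2 fell (-1.38 ± 0.17). Large rises were at Derl3 (7.48 ± 1.26), Hoxb9, a thoracic and lumbar homeobox gene (5.90 ± 0.93; chromosome 11, 96271457 to 96276595, plus strand), and the growth factor gene Fgf3 (4.74 ± 1.07), and large falls at the chemokine receptor Cxcr4 (-4.04 ± 0.59) and Pigz, of GPI anchor synthesis (-3.21 ± 0.33).

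Altogether 696 genes changed in NIP at 12 h, 438 up and 258 down. The count was 2083 with the block (1116 up, 967 down), 1141 by DESeq2, and 111, 219, 163 and 236 without untreated replicates 1 and 2 and CPA replicates 1 and 2. Of the 29 genes named in the text that passed, 17 passed without untreated replicate 1, 18 without untreated replicate 2, 19 without CPA replicate 1 and 21 without CPA replicate 2. Those that missed at least once, with the highest adjusted p, were Hoxb9 (0.0749), Slc7a11 (0.203), Fgf3 (0.235), Hoxb4 (0.122), Lhx4 (0.305), Hrk (0.381), Spcs2 (0.0633) and Hspa9 (0.14) without untreated replicate 1, Sprr1a (0.0833), Derl3 (0.0588) and Atp2a2 (0.229) without untreated replicate 2, Adcyap1 (0.0969) without CPA replicate 1, and Tubb2b (0.117) without CPA replicate 2. Hrk also missed with DESeq2 size factors (adjusted p = 0.053), the stricter filter (0.0577), NIP libraries alone (0.0842) and without the 20 most abundant genes (0.0563), and Lhx4 without the low count filter (0.0851).

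After 36 h of CPA in NIP cultures, amino acid genes had the most members changed of the lists. Of 30 genes 28 rose (29 adjusted over the list alone and with the block, median 1.86, camera adjusted p = 7.57e-64, and 0.00588 with an estimated correlation). Among them were Slc6a9 (3.99 ± 0.50), Slc7a5 (2.54 ± 0.32), the alanine aminotransferase Gpt2 (2.07 ± 0.26) and the cysteine tRNA ligase Cars (1.75 ± 0.23), each at an adjusted p of 0.00356. ATF4 and CHOP targets rose in 11 of 19 (17 over the list alone, 16 with the block, median 2.35, camera adjusted p = 8.66e-26, and 0.00588 with an estimated correlation). Examples were the secreted glycoprotein gene Stc2 (4.77 ± 0.72) and Trib3 (4.59 ± 0.79). Atf3 had 1.01 ± 0.33 (adjusted p = 0.162; 0.0174 with the block). Hspa5 was at 1306 ± 77.0 CPM against 318.5 ± 18.8 CPM (2.04 ± 0.28; adjusted p = 0.00356), with Sdf2l1 (2.66 ± 0.32) and Herpud1 (2.23 ± 0.30). ER chaperones rose in 14 of 29 (21 over the list alone, 21 with the block, median 1.17, camera adjusted p = 6.19e-32, and 0.00687 with an estimated correlation). Degradation genes rose in 4 of 22 (9 over the list alone, 8 with the block, camera adjusted p = 2.58e-06, and 0.0168 with an estimated correlation). ER protein entry genes rose in 2 of 25 (14 up and 1 down over the list alone, 11 and 1 with the block, camera adjusted p = 1.46e-09, and adjusted p = 0.15 with an estimated correlation). UPR factors rose in 4 of 12 (5 over the list alone, 6 with the block, camera adjusted p = 2.99e-08, and 0.0168 with an estimated correlation). They included Ddit3 (3.35 ± 0.47), Atf4 (1.86 ± 0.29) and Xbp1 (1.26 ± 0.21).

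Spinal genes fell in 3 of 11 cases in NIP at 36 h: Isl2 (-1.87 ± 0.36), Lhx4 (-2.76 ± 0.62) and Hoxb4 (-1.21 ± 0.29) (4 over the list alone, 6 with the block). The spinal genes had a camera adjusted p of 2.61e-05, and adjusted p = 0.0664 with an estimated correlation. Isl2 also belongs to the shared motor neuron list, where it was the 1 of 16 that fell (2 over the list alone, 7 with the block, median -0.72, and -0.41 without both high-Rn45s libraries). The shared list had a camera adjusted p of 3.14e-05, and adjusted p = 0.282 with an estimated correlation. The potassium channel Kcna2 fell (-1.97 ± 0.35), the 1 of 26 ion channel genes to do so (2 over the list alone, 4 with the block, median -0.38, camera adjusted p = 2.46e-05, and adjusted p = 0.274 with an estimated correlation). The calcium pump Atp2b4 was lower than in untreated cultures (-1.80 ± 0.26), as was Hrk (-1.14 ± 0.27), which had been higher at 12 h. Large changes elsewhere were rises at Fam129a (6.00 ± 1.03), Trim66 (5.96 ± 0.88) and Hoxb9 (5.62 ± 1.04), and falls at the glycine receptor subunit Glra2 (-4.74 ± 0.78), cysteine dioxygenase Cdo1 (-3.47 ± 0.49) and tenascin-R, Tnr (-3.35 ± 0.46). These are differences from untreated cultures at 36 h, in which Atp2b4, Hrk, Kcna2 and Tnr had risen from 0 h (2.14, 1.69, 2.07 and 3.53) and the amino acid list had fallen (median -1.22). Markers of other cells had medians of 0.37 for proliferation, -0.19 for pluripotent, 1.11 for mesenchyme and 0.95 for endoderm and endothelium genes, and none of these lists passed (camera adjusted p = 0.297, 0.81, 0.172 and 0.216). The endoderm and endothelium median was -0.36 in replicate set 1 and 0.97 in set 2. Without both high-Rn45s libraries the 4 medians were 0.04, -0.29, 0.98 and 0.36.

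In all 344 genes changed in NIP at 36 h, 197 up and 147 down. The count was 1517 with the block (755 up, 762 down), 702 by DESeq2, 1 without untreated replicate 1, the high-Rn45s library, 50 without untreated replicate 2, 151 without CPA replicate 1, 188 without CPA replicate 2, and 5 without both high-Rn45s libraries (663 with the block, 257 up and 406 down). Of the 26 genes named in the text that passed, 0 passed without untreated replicate 1 (lowest adjusted p = 0.0608), 12 without untreated replicate 2, 20 without CPA replicate 1 and 20 without CPA replicate 2. Hrk also missed with the stricter filter (adjusted p = 0.0528), without the 20 most abundant genes (0.0536) and with NIP libraries alone (0.081). Isl2 and Hoxb4 missed with NIP libraries alone (adjusted p = 0.0523 and 0.0801), and Lhx4 and Hoxb4 without the low count filter (0.057 and 0.0743). Without both high-Rn45s libraries the medians of the amino acid, ER chaperone, spinal and shared motor neuron lists were 1.82, 1.04, -1.01 and -0.41.

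**Figure D2:**
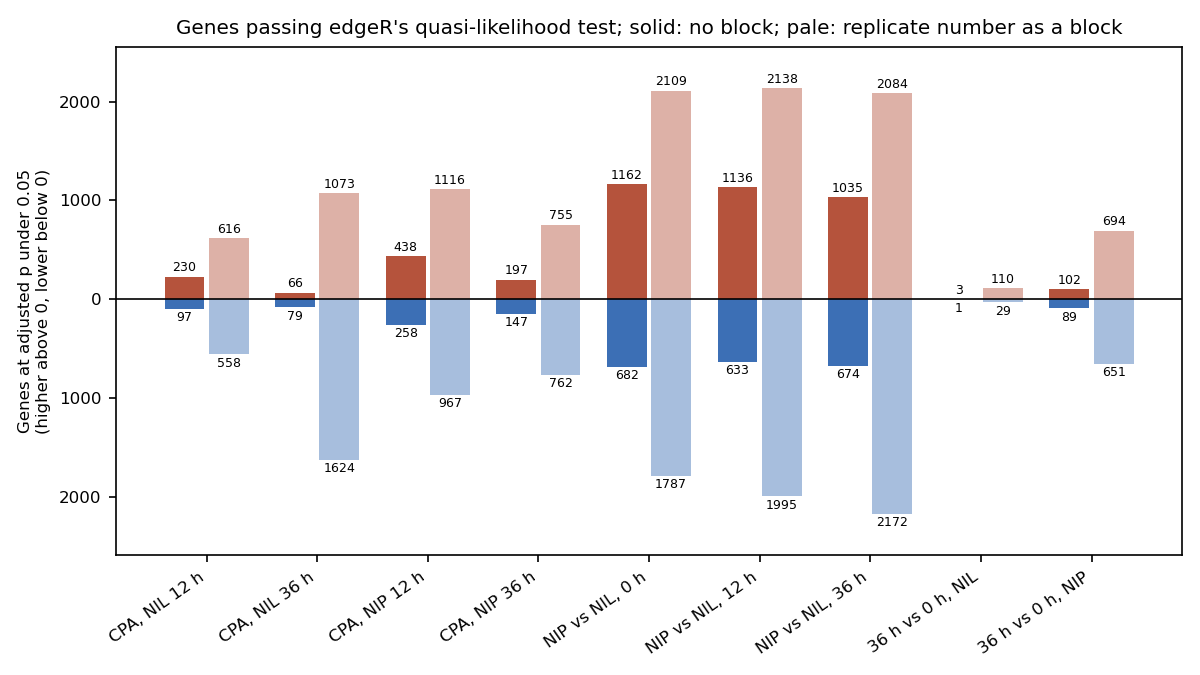
Genes with an adjusted p under 0.05 in 9 comparisons (edgeR quasi-likelihood test), higher above 0 and lower below 0 on a linear axis; solid bars are the fit on group means and pale bars the fit with the replicate number as a block. In NIL after 36 h of CPA the counts were 66 and 79 without the block and 1073 and 1624 with it.

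The CPA responses of both lines went largely the same way across genes. Log2 changes in NIL and NIP correlated at r = 0.61 (Spearman 0.61) over 14792 genes at 12 h and r = 0.53 (Spearman 0.58) at 36 h; genes are not independent replicates. Within replicate sets 1 and 2 alone r was 0.63 and 0.49 at 12 h, and 0.33 and 0.57 at 36 h. At 12 h 191 genes rose in both lines (6.81 by chance) and 53 fell in both (1.69 by chance), and at 36 h 46 rose (0.879 by chance) and 19 fell (0.785 by chance), with 0 in opposite directions. With the block 501 rose and 318 fell in both lines at 12 h, and 367 and 391 at 36 h. With the block 1 gene was higher in NIL and lower in NIP at 12 h, and at 36 h 5 were higher in NIL and lower in NIP and 6 the other way. The test of the difference in response found 0 genes at 12 h by edgeR, 0 with the block and 7 by DESeq2. At 36 h it found 0 by edgeR, 19 with the block (12 higher and 7 lower in NIP) and 18 by DESeq2. Without the block 349 and 651 genes had an unadjusted p under 0.05, less than the share of 0.05 of 14792 that chance gives. The p-values of that fit thus ran high, and its counts of 0 do not show equal responses. Without NIP 12 h untreated replicate 1 the 12 h count was 1, and without NIP 36 h CPA replicate 1 the 36 h count was 1. For Hspa5 the difference in response, NIP minus NIL, was 0.04 ± 0.38 at 12 h and -0.15 ± 0.38 at 36 h (adjusted p = 1 at both times).

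Amino acid genes responded less in NIP than in NIL at 12 h, with a median difference of -0.51 (camera adjusted p = 4.13e-17, adjusted p = 0.221 with an estimated correlation). No member passed over all genes by edgeR and 2 did over the list alone; Psat1 had -2.14 ± 0.55 and Slc7a5 -1.67 ± 0.43 (adjusted p = 1). At 36 h the same list had a median difference of 0.46 toward NIP (0 members, also over the list alone, camera adjusted p = 3.47e-07, and adjusted p = 0.566 with an estimated correlation). Gpt2 had 1.17 ± 0.36 (adjusted p = 0.733). The 22 cholesterol genes had a median difference of 0.66, and 0.36 without both high-Rn45s libraries (0 members, also over the list alone, camera adjusted p = 1.7e-07, and adjusted p = 0.566 with an estimated correlation). Among the 19 genes that passed with the block at 36 h, the response was lower in NIP for Atp2b4 (-1.97 ± 0.37, adjusted p = 0.328, 0.0349 with the block) and Hoxb4 (-2.09 ± 0.43, adjusted p = 0.328, 0.0497 with the block). It was also lower for Thbs1, a matrix glycoprotein chosen after its values were seen (-3.84 ± 0.64, adjusted p = 0.278, 0.0139 with the block). Atp2b4 and Thbs1 had risen from 0 h in untreated NIP at 36 h (2.14 and 3.12), a group that holds a high-Rn45s library. The 19 became 6 with the block without both high-Rn45s libraries.

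Between 12 h and 36 h of CPA a few genes changed their response, and the genes in this paragraph are named in the separate 12 h and 36 h comparisons because of that test, after their values were seen. Fgf15, a fibroblast growth factor gene (chromosome 7, 144896531 to 144900953, plus strand), rose in NIP at 12 h (3.11 ± 0.592 to 33.5 ± 7.74 CPM; 3.43 ± 0.34, adjusted p = 0.000164) and fell at 36 h (7.73 ± 2.38 to 2.23 ± 0.492 CPM; -1.77 ± 0.34, adjusted p = 0.0161), a difference of -5.19 ± 0.48 (adjusted p = 0.00078). Nrn1, encoding the neurite growth factor neuritin, fell at 12 h (-1.34 ± 0.19; adjusted p = 0.002) and had 0.67 ± 0.19 at 36 h (adjusted p = 0.095; 0.0186 with the block), a difference of 2.01 ± 0.27 (adjusted p = 0.0289). In NIL Arid5a, an RNA-binding protein gene, rose at 12 h (1.25 ± 0.15; adjusted p = 0.000668) and had -0.39 ± 0.15 at 36 h (adjusted p = 0.211), a difference of -1.64 ± 0.21 (adjusted p = 0.0356). In NIP the response at 36 h was lower than at 12 h for Atf3 by -3.10 ± 0.47 (adjusted p = 0.0796; 0.000652 with the block), Hrk by -2.15 ± 0.38 (0.133; 0.01 with the block) and Sel1l by -1.15 ± 0.25 (0.237; 0.0306 with the block).

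In NIP the response of degradation genes was lower at 36 h than at 12 h (median difference -0.42; 0 of 22 members, 1 over the list alone and with the block, camera adjusted p = 1.04e-07, and 0.017 with an estimated correlation). The response of axon injury genes was also lower (median -0.17, mean -0.73; 0 of 19 members, 1 up and 5 down over the list alone and with the block, camera adjusted p = 8.62e-06, and 0.0109 with an estimated correlation). In NIL ER chaperones (median -0.47; 0 of 29, also over the list alone, 1 down with the block, camera adjusted p = 9.16e-08, and adjusted p = 0.324 with an estimated correlation) and amino acid genes (-0.62; 0 of 30, also over the list alone, camera adjusted p = 6.57e-11, adjusted p = 0.324 with an estimated correlation) had lower responses at 36 h. In NIL 1 gene differed, 16 with the block (1 higher and 15 lower) and 10 by DESeq2. The count was 0 with NIL libraries alone, without a low count filter, with a stricter one or without the 20 most abundant genes. Without the block 622 genes had an unadjusted p under 0.05, again less than the share of 0.05 that chance gives. In NIP 2 differed (848 unadjusted; 161 with the block, 81 and 80, and 75 by DESeq2), 1 with NIP libraries alone and 4 without the low count filter. Arid5a passed without NIL 12 h CPA replicate 2 (adjusted p = 0.0212) and missed without each of the other 7 libraries (0.0858 to 0.544). Fgf15 passed without each of 8 libraries, and Nrn1 without untreated NIP 36 h replicate 1 or CPA-treated NIP 36 h replicate 2 and missed without each of the other 6 (adjusted p up to 0.344, without NIP 12 h CPA replicate 2).

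Untreated cultures had few calls by 12 h. The unadjusted counts given next were below the share of 0.05 of 14792 genes that chance gives, so these p-values ran high. No gene passed by edgeR in NIL (119 at an unadjusted p under 0.05; 0 with the block and 0 by DESeq2) or NIP (350 unadjusted; 0 with the block, 1 by DESeq2, which was Fos, and 1 without NIP 12 h untreated replicate 2). Immediate early genes, which respond to stimulation, had medians of -0.46 in NIL (0 of 18 members, 4 lower over the list alone, camera adjusted p = 6.26e-14, and adjusted p = 0.0927 with an estimated correlation) and -0.80 in NIP (0 and 4, camera adjusted p = 7.45e-13, and adjusted p = 0.0631 with an estimated correlation). Fos had -1.98 ± 0.47 and -2.30 ± 0.47 (adjusted p = 1 in both). Amino acid genes had a median of -0.52 in NIP (0 of 30, also over the list alone, camera adjusted p = 3.88e-23, and adjusted p = 0.0838 with an estimated correlation).

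By 36 h untreated NIL cultures had 4 genes changed: the glutamate receptor Grm7 (2.28 ± 0.31), the vesicular transporter Slc6a17 (1.82 ± 0.24) and the actin-binding gene Dmtn (1.06 ± 0.14) rose, and Crabp2, a retinoic acid binding protein, fell (-2.71 ± 0.32; adjusted p = 0.0142). Neural progenitor genes had a median of -0.98 (0 of 14, 4 lower over the list alone, 2 with the block, camera adjusted p = 2.1e-09, and adjusted p = 0.118 with an estimated correlation). Fabp7 had -2.18 ± 0.44 (adjusted p = 0.159; 0.0122 with the block) and the intermediate filament gene Nes -1.81 ± 0.39 (0.167; 0.0346 with the block). The count of 4 (855 at an unadjusted p under 0.05) was 139 with the block (110 up, 29 down), 94 by DESeq2 and 0 with NIL libraries alone in the fit. Of these genes 0 passed without NIL 0 h replicate 1 or 2 or untreated 36 h replicate 1 (lowest adjusted p = 0.0563), and 1 passed without untreated 36 h replicate 2.

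In untreated NIP cultures amino acid genes fell by 36 h from their higher 0 h level, and a difference between the lines in the change over time was not tested. Of 30 amino acid genes 14 fell (29 adjusted over the list alone, 26 with the block, median -1.22, camera adjusted p = 5.97e-41, and adjusted p = 0.0501 with an estimated correlation). Among them were Psat1 (-2.80 ± 0.41), Slc7a5 (-1.87 ± 0.31) and Cars (-1.37 ± 0.23). ATF4 and CHOP targets fell in 2 of 19 (10 over the list alone, 11 with the block, median -1.22, camera adjusted p = 1.68e-08, and adjusted p = 0.213 with an estimated correlation). Cholesterol genes fell in 2 of 22 (13 and 15, median -0.99, camera adjusted p = 1.21e-13, and adjusted p = 0.255 with an estimated correlation). Immediate early genes fell in 3 of 18 (5 and 7, median -0.85, camera adjusted p = 0.00153, and adjusted p = 0.399 with an estimated correlation). Without both high-Rn45s libraries 0 members of these 4 lists passed by edgeR, and with the block as well 11 amino acid, 3 ATF4 and CHOP, 0 cholesterol and 4 immediate early genes fell (medians without the block -1.22, -1.18, -1.01 and -0.55). Examples of immediate early genes were Fos (-2.27 ± 0.48) and Egr3 (-2.72 ± 0.59). Ion channel genes rose in 2 of 26, Kcna2 among them (2.07 ± 0.36) (3 over the list alone, 8 with the block, median 0.61). Channel genes had a camera adjusted p of 6.07e-09, and adjusted p = 0.213 with an estimated correlation. Atp2b4 (2.14 ± 0.26), Hrk (1.69 ± 0.28) and Syn2 (1.73 ± 0.30) rose, as did the matrix genes Tnr (3.53 ± 0.47) and Thbs1 (3.12 ± 0.48) and the protease inhibitor A2m (4.22 ± 0.77), and the progenitor genes Sox9 (-4.14 ± 0.76) and Vim (-1.16 ± 0.18) fell. In all 191 genes changed, 102 up and 89 down (1345 with the block, 694 and 651; 630.0 by DESeq2). The count was 0 without NIP 0 h replicate 1, 35 without NIP 0 h replicate 2, 1 without untreated 36 h replicate 1, the high-Rn45s library, and 31 without untreated 36 h replicate 2, and 1 without both high-Rn45s libraries (443 with the block). Of the 14 genes named that passed, 0, 3, 1 and 3 passed without these 4 libraries in turn.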

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

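In this part, the split of amino acid genes into untreated and treated levels was chosen after the result was seen. The test without both high-Rn45s libraries was set down before its own result was seen.

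A difference in CPA response between lines or times drew attention to each result here. Between 12 h and 36 h of CPA, the response of Fgf15 in NIP changed by -5.19, that of Nrn1 in NIP by 2.01 and that of Arid5a in NIL by -1.64 on the log2 scale, each past the test of the difference. The list of ER-associated degradation genes changed its response in NIP by a median of -0.42 and the axon injury list by -0.17 (-0.45 and -0.6 without both high-Rn45s libraries). The amino acid list had a median difference in response, NIP minus NIL, of -0.51 at 12 h and 0.46 at 36 h, calls that were lost with an estimated correlation (adjusted p = 0.221 and 0.566) and by fry (0.513 and 0.528). With the replicate block 19 genes differed in response between the lines at 36 h. Groups hold 2 libraries, so no library was tested as far from its group and other splits of the libraries cannot be counted.

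By camera with the preset correlation alone, amino acid genes responded less in NIP than in NIL at 12 h and more at 36 h, and no member passed over all genes by edgeR or with the block (adjusted p = 0.221 and 0.566 with an estimated correlation). At 36 h NIP minus NIL was 0.12 in untreated cultures and 0.65 in treated ones (list medians, spread 0.07 and 0.065), so untreated NIP was not the lower line there. At 12 h the treated cultures differed by 0.26 (spread 0.044) and the untreated by 0.84, so the smaller rise in NIP went with a higher untreated level. These values are the parts of which the difference in response is made, so they cannot test its cause. The high-Rn45s libraries stay open for 36 h: without both the median difference was 0.35 (spread 0.089) against 0.46 with all libraries, too close to the bound of 0.3 set beforehand to decide. A difference between the cell types in how these genes respond to CPA is the biological explanation the design gives. It was not tested apart from the untreated levels and the high-Rn45s libraries.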

How the results depend on the processing

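The fits without both high-Rn45s libraries, with and without the block, were added after seeing the data; the other alternatives were planned. Of 194 gene values named in the text, 170.0 passed, and the sign differed from the reported one in 7 cases, at 2 values near 0. Lhx3 in NIL at 36 h of CPA (-0.03) was 0.00 with NIL libraries alone, 0.23 without both high-Rn45s libraries, 0.09 with the block as well, and -0.32 to 0.22 with a library left out. The difference in the response of Hspa5 at 12 h ranged from -0.21 to 0.32 with a library left out. Among the named genes, calls were lost in 33 cases with 1 line alone, 60.0 without both high-Rn45s libraries (5 with the block), 11 without the low count filter, 7 without the 20 most abundant genes, 6 with the stricter filter and 4 with DESeq2 size factors, and gained in 14 with the block and 12 by DESeq2. DESeq2 size factors in edgeR moved no total count by over 1.5 times (in NIL at 36 h of CPA 79 falls became 49), and the median log2 change of all genes ran from -0.04 to 0.06 over the scalings.

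With the replicate block, CPA counts were 1174, 2697, 2083 and 1517 (NIL 12 h and 36 h, NIP 12 h and 36 h, against 327, 145, 696 and 344), 19 for the difference between lines at 36 h, 16 and 161 for the difference between times in NIL and NIP, 3896, 4133 and 4256 between untreated lines, and 139 and 1345 for 36 h of culture. Beyond the calls given beside the results, the block changed no call of a gene or list named in the text. With both high-Rn45s libraries also out, these were 1087, 404, 1961, 663, 6, 0, 31, 3697, 3953, 3181, 132 and 443. Without those libraries and without the block, they were 0 in NIL at 36 h and 5 in NIP at 36 h of CPA, 0 and 1 between times, 840 between untreated lines at 36 h, and 1 for 36 h in NIP. DESeq2 gave 703, 700.0, 1141 and 702 for CPA, 7 and 18 between lines, 10 and 75 between times, 94 and 630.0 for 36 h of culture, and 1 for 12 h in NIP. A fit of 1 line alone gave 124 and 4 for CPA in NIL, 0 and 1 between times and 0 for 36 h in NIL, and higher counts in NIP: 763 and 491 for CPA and 249 for 36 h. Without the low count filter, counts were 83 in NIL at 36 h and 0 and 4 between times. The stricter filter gave 0 between times in NIL, and leaving out the 20 most abundant genes 84 in NIL at 36 h and 0 between times in NIL. The causes were not tested.

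With 1 library left out at a time, counts ranged from 115 to 128 in NIL 12 h, 0 to 514 in NIL 36 h, 111 to 236 in NIP 12 h and 1 to 188 in NIP 36 h of CPA, 0 to 1 between lines at both times, 0 to 1 and 1 to 3 between times in NIL and NIP, 945 to 1236, 931 to 1131 and 823 to 1040 between untreated lines, 0 to 2 for 36 h in NIL, 0 to 35 for 36 h in NIP and 0 to 1 for 12 h in NIP. Fewer libraries lower the power by construction, which would not raise a count. In the fit without a block, a group left with 1 library also sets 1 replicate set against both. Of 14792 genes, 3660 were higher and 3614 lower in set 2 by the block fit. Differences between sets therefore enter these comparisons, and how much they add to the ranges was not tested.

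Lists that passed, with the preset and then the estimated correlation, were 14 and 5, 12 and 5, 15 and 6, and 13 and 5 for CPA, 5 and 0 and 7 and 0 between lines, 17 and 0 and 8 and 2 between times, 12 and 0, 9 and 0 and 9 and 0 between untreated lines, 8 and 0 and 8 and 0 in untreated NIL, and 12 and 0 and 14 and 0 in untreated NIP. By fry they were 7 in NIP at 36 h of CPA, 0 and 0 between lines, 1 and 2 between times, 4 between untreated lines at 36 h, 0 and 0 in untreated NIL and 0 and 5 in untreated NIP. The correlation of both lines' responses at 12 h was 0.76 over genes of at least 5 CPM.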

Other observations

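Here the tests of a lower share of neurons and of the high-Rn45s library in NIL were chosen after the result was seen. The other tests were set down before theirs. The cell type marker medians after 12 h of CPA were not among the tests set down.

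Among 22 cytosolic and mitochondrial heat shock genes, 1 rose under CPA in NIL at 12 h, in NIP at 12 h and in NIP at 36 h, Hspa9, the mitochondrial Hsp70 (1.17 ± 0.19, 1.01 ± 0.19 and 1.26 ± 0.19; adjusted p = 0.00595, 0.01 and 0.00501 by edgeR). With the block 1 up and 2 down, 1 and 1, and 2 and 0 heat shock genes passed in these comparisons. In NIP at 36 h Hspa9 had an adjusted p of up to 0.0842 with a library left out. Of 31 proteasome genes 0 passed at 12 h in either line, also over the list alone and with the block, with medians of -0.23 in NIL and -0.22 in NIP (camera adjusted p = 0.00114 and 0.00254, adjusted p = 0.572 and 0.594 with an estimated correlation).

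In NIL after 36 h of CPA, neuronal lists had negative medians whose calls were lost with an estimated correlation (adjusted p = 0.123 to 0.299), and endoderm and endothelium genes a positive median that did not pass (camera adjusted p = 0.0746). A lower share of neurons in the treated cultures may account for part of this, and the values cannot decide it. The medians of the proliferation, pluripotent, endoderm and mesenchyme lists were 0.42, 0.63, 0.81 and 0.88 (0.96, 1.25, 1.42 and 1.07 in replicate set 1, and 0.22, 0.50, 0.39 and 0.69 in set 2), all above 0. They lay within 0.5 of each other, but that bound was set after they were seen and could not fail. Lhx3 had -0.03 ± 0.32, an error too wide to show that it stayed level. Its counts also cannot separate an inserted sequence from the cell's own copy. The medians were 0.05, -1.42, 0.43 and 0.16 without both high-Rn45s libraries, where a CPA library of set 1 faces untreated libraries of both sets. The lists of neural progenitors and of astrocytes and oligodendrocytes were left out of the test (0.31 and 0.13 in that fit). More cells of a parietal or primitive endoderm kind cannot be told apart from a lower share of neurons. A marker set fixed before its values were seen had a median of 0.48 (spread 0.16, with 1.08 in replicate set 1 and 0.26 in set 2), close to the bound of 0.5. The set also had 0.50 in NIP after 36 h of CPA (-0.41 and 0.70 in sets 1 and 2) and 0.51 in untreated NIL from 0 h to 36 h. The high-Rn45s library of replicate set 2 is argued against as the whole source, since in set 1 alone the synaptic and cytoskeleton medians were -0.62 and -0.67 (spread 0.11 and 0.076). A loss of neuronal transcripts within the neurons under CPA stays open and was not tested.

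Of the genes that rose after 12 h of CPA, 66 had under 1 CPM in the untreated cultures of the line in which they rose (18 in NIL, 59 in NIP, 11 in both). Reads running on from an expressed gene that ends within 50 kb upstream on the same strand are argued against as the general source. Of the 63 with a position, 36.5% (23, exact 95% interval 24.7% to 49.6%) had such a gene of at least 5 CPM, against 34.7% of 952 other genes with few counts. Overlapping genes, the other strand and longer distances were not looked at, and the strand setting of the counts is not known. The median effect of set 2 over set 1 on these genes was -0.035 (spread 0.075), inside the bound of 0.3 set beforehand. That bound was a poor choice, as members went both ways (quartiles -0.33 and 0.28) and the test that picked the genes favours those whose sets agree. The planned test therefore cannot decide. Kinds of cells lower in set 2 were not looked at. Markers of the kinds higher in set 2, which were not part of the planned test, showed no general rise. After 12 h of CPA their medians in NIL and NIP were -0.42 and -0.18 for pluripotent, -0.09 and 0.01 for proliferation and 0.17 and -0.13 for endoderm and endothelium genes. These come from the fit without both high-Rn45s libraries, which are not 12 h libraries. The endoderm marker set fixed beforehand had -0.01 and -0.14. Other sources were not tested, and the pattern was found and tested on the same libraries.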
